A study of Mus musculus with 12 samples.

How the data were processed

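RNA was measured by sequencing in 12 samples of mouse embryonic stem cells, the pluripotent cells of the early embryo kept in culture, here with serum, leukemia inhibitory factor and 2i, a pair of kinase inhibitors, per the labels' protocols. The samples form 6 groups of 2 libraries. In the first set a codon-altered transgene for mDUX, a mouse double-homeobox transcription factor, or a control was expressed transiently for 24 h and read as 50 bp single-end reads. In the second set the same transgene, with an HA tag, sat in a doxycycline-inducible lentivirus in a line that also carried a MERVL::EGFP reporter, a green fluorescent protein gene driven by the endogenous retrovirus MERVL. That stable line was sequenced unsorted, with doxycycline for 24 h or without it, and after 24 h of doxycycline and sorting into GFP-positive and GFP-negative cells, as 125 bp paired-end reads. Libraries were made from poly(A) RNA with a stranded kit, per the labels' protocols. Nothing in the labels says whether the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

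Novoalign 2.8, DESeq2 and the genome build mm10 are named, with no role or order, per the submitters' processing notes. The authors deposited 3 tables of raw read counts, one per comparison, per the file headers. The counting tool, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Each table listed Ensembl genes and repeat families: 27776 genes and 1488 repeat families in the transient table, and 27590 genes and 1492 repeat families in each stable-line table. The deposited log2 fold changes and adjusted p-values of the authors' own comparisons stand beside the counts, per the file headers, and were used only to count the authors' calls. Against the counts, the authors' log2 values ran from mDux over control in the transient table, and from no doxycycline over doxycycline and from GFP-negative over GFP-positive in the others. The rlog columns were not used. Dates made by a spreadsheet stood in place of 27 gene symbols in all 3 tables and these genes were named from the reference, while 400 genes of the stable-line tables had an empty symbol and were named by their identifier.

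Column names index the 2 libraries of a group from 0 while sample titles count from 1, so a column was tied to its group and not to a numbered replicate. The sample labels give the transient controls the same transgene as the transient mDUX samples, while titles and column names call them control; the groups follow the titles, so every transient fold change rests on them. The libraries are called A and B. The counted reads per library came to 17914954 to 21988401 in the transient set, 14365741 to 18388836 in the unsorted set, and 31870748 to 53826590 in the sorted set. The biological coefficient of variation was 11.9% in the transient, 3.8% in the unsorted and 5.0% in the sorted comparison. Over genes with 20 or more reads, the libraries of every group differed by more than sampling noise, with a chi-square per degree of freedom of 1.81 to 30.6, so none was treated as a duplicate.

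Counts were tested with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood F-test (glmQLFit with robust estimation, glmQLFTest). Each main comparison was fitted on its own 4 libraries. Genes and repeat families were kept by filterByExpr with a minimum count of 10 and a minimum total of 15. Genes and repeat families were fitted together, with the library size and the TMM factor taken from genes alone, and p-values were adjusted by Benjamini-Hochberg separately over genes and over repeat families, with a threshold of 0.05. CPM values are scaled to the gene reads of each library, not to all reads, after TMM scaling within a comparison's own fit, so levels of different comparisons are on different scales. The standard error of a log2 fold change was taken as its size divided by the square root of F. The GFP-negative cells were set against uninduced cells in a joint fit of the 8 stable-line libraries, and the differences between effects were interaction contrasts in fits of 8 libraries. Where all libraries of a group had 0 reads, a fold is given as a lower bound against a floor of 3 counts over the group. Standard deviations and standard errors include the spread between the 2 libraries of a group, while floors cover counting error only. Coordinates are from the GENCODE annotation of GRCm38, the assembly also called mm10.

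Before the data were examined, 23 gene lists, the comparisons, most alternatives and the rule for named genes were fixed. Lists were tested with camera from limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01, where at least 5 members were tested. They were tested again with an estimated correlation. That version uses only the residual degrees of freedom of the fit, few with 4 libraries, so even strongly changed lists can fail it. The lists were cleavage-stage, oocyte, naive pluripotency, primed epiblast, primitive endoderm, trophectoderm, neuroectoderm, mesoderm, fibroblast or feeder, blood and endothelial, repressors of MERVL and cleavage genes, p53 targets, integrated stress response, interferon response, G2/M, G1/S, germline genes sensitive to methylation, ribosome and nucleolus, splicing factors, glycolysis, oxidative phosphorylation, histone, and mitochondrially encoded genes. The named genes were, per comparison and direction, the 10 largest log2 fold changes past the threshold with a mean of at least 5 CPM in the higher group and libraries that did not overlap, with at most 4 predicted genes. To these were added up to 4 members of each list with the smallest adjusted p, or up to 2 with the highest level where none passed, a set of genes always reported, and for each interaction the 5 largest differences in each direction. The text prints a selection of these. Repeat families were tested for the first time after the tables were seen, and those named were chosen then. Dux, one of the genes always reported, is listed in the tables as Duxf3. The transgene is codon-altered, so Duxf3 counts do not check its expression.

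The edgeR script was tested on simulated data with 200 changed genes per comparison. Of genes changed 2-fold it called 80% in the transient simulation of 15031 genes, 78% in the unsorted simulation of 16262 genes and 82% in the sorted simulation of 16350 genes. It made 23, 4 and 10 false calls in these simulations, where DESeq2 made 11, 2 and 3. The simulated changes were few and ran equally in both directions. They do not check calls where most genes change, as in the unsorted comparison with 10576 of 16229 genes called. The alternatives were RLE size factors, the DESeq2 1.42.0 Wald test, no filter, a filter of CPM 1 in 2 libraries, a 2-fold minimum, one spread over the 8 stable-line libraries, and leaving out each library. Gene totals with no composition factor, TMM over genes and repeats together, and a block by column index were chosen after seeing the data. Summaries were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1.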

Results

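The tables held 12 libraries in 6 groups of 2. Values below are CPM, mean ± SD over n = 2 libraries, and log2 fold changes with their standard error. Adjusted p is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Members of the Zscan4, Usp17l, Tdpoz, Tcstv, Obox and Duxf families share near-identical sequence, and the treatment of reads with several matches is not given in the sources used here, so the counts of single members are uncertain. The same holds for repeat families as a class.

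The transient comparison asked which transcripts change after 24 h of mDUX expression relative to the control. Cleavage-stage genes, which are active in the early embryo, made up the clearest group: 41 of 52 tested members rose and none fell, with a median log2 fold change of 2.97. Adjusted over the list alone, 47 rose. Zscan4d, a SCAN and zinc-finger gene marking 2-cell-like cells (chromosome 7, 11161374 to 11166159, GRCm38), rose from 32.0 ± 0.376 to 387 ± 6.41 CPM (log2 fold change 3.60 ± 0.10, adjusted p = 1.34e-05). Zfp352 (chromosome 4, 90218820 to 90225702) rose 13.1-fold, from 6.15 ± 0.669 to 80.3 ± 0.987 CPM, and Tcstv3 rose 13.0-fold. Zscan4c rose 8.27-fold and Usp17lb 12.8-fold. Tcstv1 had a log2 fold change of 2.97 ± 0.63 and did not pass (adjusted p = 0.0764), though it passed without control A (0.0307) or control B (0.00499). Duxf3, the endogenous Dux gene (ENSMUSG00000075046, chromosome 10, 58229979 to 58232675), rose from 0.514 ± 0.0899 to 2.58 ± 0.914 CPM (adjusted p = 0.0242), a call lost without mDux library B (adjusted p = 0.156).

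The largest change among genes of at least 5 CPM was that of Cspg4, a transmembrane proteoglycan gene, from 0.0883 ± 0.0569 to 8.71 ± 1.17 CPM. Spz1 rose 17.8-fold, Cpb2 14.5-fold, Nat8f2 13.6-fold, Cntnap3 13.2-fold and Klhl6 12.9-fold. Of the pluripotency list, Fbxo15 rose 1.82-fold and Dppa2 1.47-fold, and the other 28 of 30 members did not pass. The core factors Pou5f1, Nanog and Sox2 had log2 fold changes of 0.09 ± 0.12, 0.02 ± 0.09 and -0.05 ± 0.09, Klf4 -0.11 ± 0.10 and Zfp42 -0.04 ± 0.09. Oocyte genes Nlrp4f and Dppa3 rose 2.09-fold and 2.97-fold, out of 7 tested. The calls of Nlrp4f (adjusted p = 0.0653 and 0.123), Dppa2 (0.395 and 0.916) and Zfp809 (0.0537 and 0.106) were lost without mDux library A or B, and those of Dppa3 and Fbxo15 without mDux library B (adjusted p = 0.198 and 0.0548). Zfp809, which encodes a zinc-finger repressor of retroviruses, was the 1 of 26 repressor genes to rise (1.83-fold). Cycs, encoding cytochrome c, was the 1 of 24 oxidative phosphorylation genes to rise (2.50-fold), and Col6a1 the 1 of 11 fibroblast genes.

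In all, 319 of 14979 genes rose and 1 fell, Gm22701 (log2 fold change -1.13 ± 0.17, adjusted p = 0.010), a call lost without either mDux library (0.145 and 0.117), and 974 genes had an unadjusted p under 0.05. DESeq2 called 2 genes lower. Of 22 lists tested with camera, 1 passed, the cleavage-stage list (adjusted p = 4.41e-99), and with an estimated correlation its adjusted p was 0.0568. The estimated correlation was 0.0156 against the preset 0.01, so the higher adjusted p rests mainly on the few degrees of freedom of that version. None of the histone (25 tested), stress response (24), p53 (25), G2/M (25), G1/S (27), germline (22), ribosome (35), splicing (33), glycolysis (18), interferon (13), epiblast (12), endoderm (14), trophectoderm (15), neuroectoderm (6), mesoderm (10), blood (4) or mitochondrial (7) members passed. Control library A carried 2.346% ribosomal repeat reads against 0.077% in control library B. The counts depended on single controls: without control A, 522 genes rose and 92 fell, and without control B, 1185 rose and 1404 fell. Without control B the histone list had 9 members higher and 2 lower, the G2/M list 2 and 8, and the stress response list 6 higher.

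The unsorted comparison asked what 24 h of doxycycline changed in the stable line. No group had doxycycline without the transgene, so effects of the drug and of mDUX cannot be told apart in this comparison. Both sorted groups had doxycycline. Of 54 cleavage-stage genes tested, 51 rose with a median log2 fold change of 9.39, or 9.23 with the 5 members at 0 reads without doxycycline set at their bound. Cpt1c fell (log2 fold change -0.27 ± 0.09), a call not made by DESeq2 or without no-doxycycline library B or doxycycline library B, and Patl2 and Zfp750 did not pass. Adjusted over the list alone, 52 rose. Zscan4d rose from 2.35 ± 0.56 to 4110 ± 56.6 CPM (log2 fold change 10.75 ± 0.11, adjusted p = 3.32e-196), Zscan4c 988-fold, Zfp352 1260-fold and Tcstv3 1410-fold. Duxf3 rose from 0.253 ± 0.104 to 53.1 ± 7.76 CPM. Genes with 0 reads without doxycycline included AF067063 (chromosome 13, 119827961 to 119830216), at least 677-fold higher, Fam90a1a, at least 645-fold higher, the olfactory receptor genes Olfr376 and Olfr881, at least 536-fold and 439-fold higher, and Tmem212, at least 393-fold higher.

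Pluripotency genes moved the other way: 19 of 30 fell, 5 rose and 6 did not pass, with a median log2 fold change of -0.58. Pou5f1 (chromosome 17, 35506018 to 35510772) went from 796 ± 14.4 to 453 ± 13.5 CPM (log2 fold change -0.81 ± 0.06). Sox2 fell by 0.92 on the log2 scale, Nanog fell by 0.69, Zfp42 fell by 0.70 and Fgf4 fell by 1.31. Fbxo15, Dppa2, Sall4, Klf5 and Klf2 were the 5 that rose, Fbxo15 by 8.55-fold and Dppa2 by 7.76-fold. Integrated stress response genes rose in 21 of 24 cases, with Psat1 lower: Atf3 rose 19.7-fold, the growth repressor Ddit4 18.1-fold, and the phosphatase subunit Ppp1r15a 7.86-fold. Histone genes rose in 22 of 24 cases (median log2 fold change 3.26), with the variants H2afy and H2afv lower. The list as a whole took 0.105% of gene reads without doxycycline and 0.154% with it. Replication-dependent histone genes took 0.00314% and 0.0348%, so the median rests largely on members at low levels. Hist1h3c went from 0.696 ± 0.308 to 27.3 ± 3.8 CPM, H1f0 rose 4.41-fold and H2afx 3.05-fold. The camera adjusted p was 1.32e-30 for cleavage-stage, 4.12e-08 for stress response, 7.43e-07 for histone and 0.000178 for pluripotency genes. With an estimated correlation these adjusted p were 0.283, 0.528, 0.618 and 0.618, and no list passed. With 4 libraries few lists could pass that version, so failing it does not decide whether a list changed.

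The p53 targets Btg2 and Pmaip1 rose 5.63-fold and 4.71-fold within a list in which 8 of 24 rose and 11 fell, and Cdkn1a, the p53-induced cell cycle inhibitor, fell by 0.32. Of G1/S genes 8 of 27 rose and 16 fell, and of G2/M genes 14 of 25 rose and 5 fell, or 10 and 11 with gene totals only. Oocyte genes rose in 3 of 10 cases and fell in 2, with Dppa3 4.29-fold higher. The falls were Ooep (log2 fold change -1.27 ± 0.07) and Khdc3 (-0.57 ± 0.12). Of 26 repressor genes 13 rose and 8 fell, Zfp809 5.81-fold higher and Mga lower by a log2 fold change of -1.08 ± 0.06. Trim28, a co-repressor of retroviruses, rose 1.62-fold, Dnmt1 fell by 0.45, and Chaf1a had a log2 fold change of 0.09 ± 0.06 (adjusted p = 0.195), or -0.13 with gene totals only. Cycs rose 13.5-fold among 24 oxidative phosphorylation genes of which 4 rose and 10 fell, and the glucose transporter Slc2a1 rose 3.87-fold among 18 glycolysis genes of which 9 rose and 4 fell. Counts for the rest, as rose, fell and tested, were: germline 10, 2 and 20, ribosome 17, 4 and 35, splicing 9, 11 and 33, interferon 3, 4 and 10, epiblast 3, 6 and 10, endoderm 7, 3 and 13, trophectoderm 5, 5 and 15, neuroectoderm 6, 1 and 7, mesoderm 2, 0 and 6, fibroblast 5, 1 and 9, and blood 1, 1 and 3. The mitochondrial genes listed had 0 reads in all 4 unsorted libraries.

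In all, 5525 of 16229 genes rose and 5051 fell, and with a 2-fold minimum 2636 and 953. The largest falls among genes of at least 5 CPM included Dpys, from 25.6 ± 0.528 to 4.25 ± 0.233 CPM, Dcdc2a, Dcstamp, Zfp72, Srgap3 and Ahnak2. With gene totals and no composition factor, the median of all genes lay at -0.22 on the log2 scale, and 4097 genes rose and 7458 fell, 35.5% of calls higher against 52.2%.

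**Figure D1:**
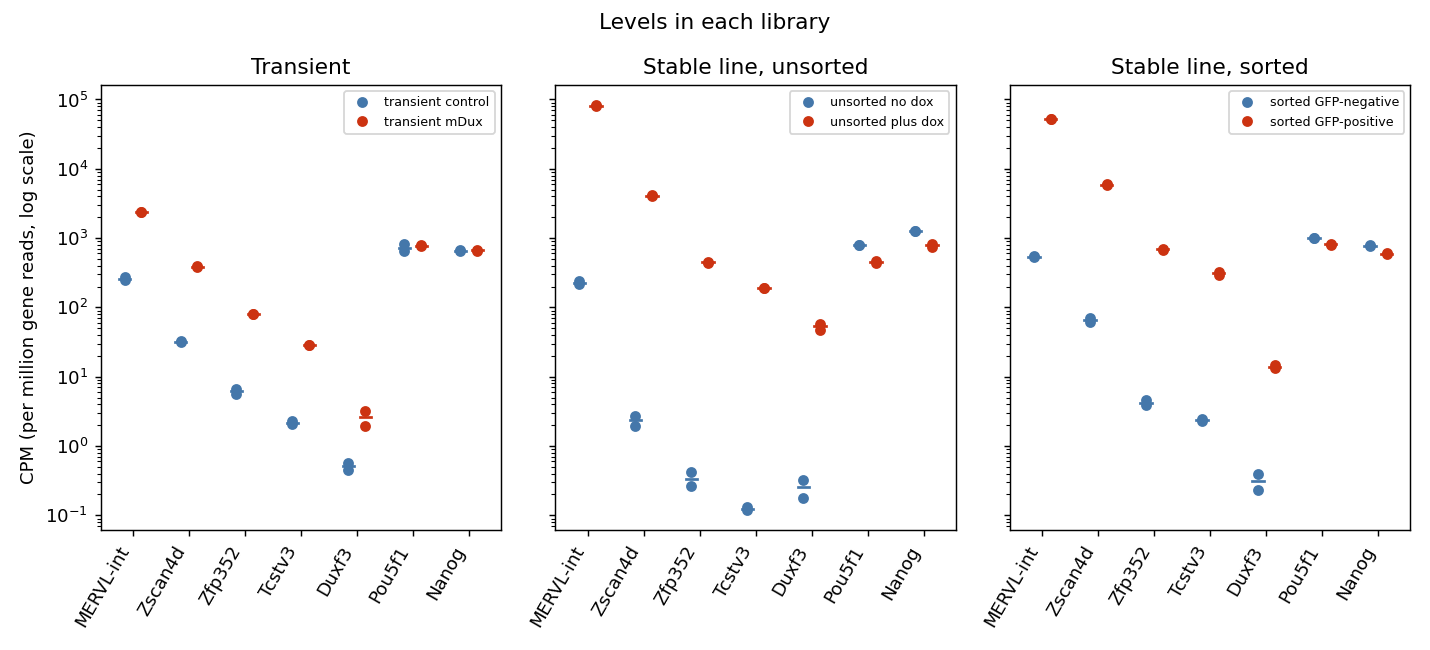
Levels of MERVL-int and 6 genes in each library, in CPM on a log axis, for the transient, unsorted and sorted comparisons, with bars at the mean of 2 libraries. Zscan4d stood at 4110 CPM with doxycycline and 2.35 without.

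The sorted comparison set GFP-positive against GFP-negative cells of the induced line. Of 57 cleavage-stage genes 54 rose in GFP-positive cells, with a median log2 fold change of 6.18, and Cpt1c, Patl2 and Zfp750 were lower. The count was the same adjusted over the list alone. The reporter that set the gate is driven by MERVL, so these genes and MERVL itself are not independent of the sort. Zscan4d stood at 5870 ± 180 CPM in GFP-positive and 66.3 ± 5.8 CPM in GFP-negative cells (log2 fold change 6.47 ± 0.07, adjusted p = 2.72e-16). Zscan4c was 74.4-fold higher, Usp17lc 111-fold, Zfp352 162-fold, Tcstv3 131-fold and Duxf3 44.1-fold. The largest changes included Esp4, Tdpoz1 (303-fold), Slc22a28 (261-fold), Drr1 (217-fold) and AF067063 (197-fold).

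Pluripotency genes were lower in 24 of 30 cases (median log2 fold change -0.65) and higher in 5. Sox2 fell by 1.22, Fgf4 fell by 1.56, Zfp42 fell by 0.80, Klf4 fell by 0.60, Nanog fell by 0.38 and Pou5f1 fell by 0.33, while Fbxo15 was 14.2-fold higher. Stress response genes were higher in 18 of 24 cases, Ppp1r15a 5.42-fold and Asns, encoding asparagine synthetase, 1.78-fold, with Nupr1, Trib3 and Gdf15 lower. Histone genes were higher in 22 of 24 cases (median 2.45), Hist1h3c 14.7-fold, with H2afy and H2afv lower. With a filter of CPM 1 in 2 libraries, 14 histone genes were higher and 1 lower, with a median of 1.44. The list as a whole took 0.12% of gene reads in GFP-negative and 0.136% in GFP-positive cells. G2/M genes were higher in 20 of 25 cases, Hmmr 2.39-fold and the cyclin Ccna2 1.93-fold, with Kif11 lower; with gene totals only, 9 were higher and 5 lower. Germline genes were higher in 16 of 23 cases, Mael 3.32-fold and Dazl 3.21-fold. Dppa3 was 28.9-fold higher among 9 oocyte genes, of which 3 were higher and 1, Ooep, lower. The camera adjusted p was 4.04e-28 for cleavage-stage, 3.63e-05 for pluripotency, 6e-05 for G2/M and for histone, 0.000312 for stress response, 0.0051 for germline and 0.049 for mitochondrial genes. With an estimated correlation the adjusted p were 0.361, 0.361, 0.439, 0.361, 0.439, 0.606 and 0.606 in that order of lists, with histone after G2/M. With 4 libraries here too, failing that version does not decide whether a list changed.

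Counts for the rest, as higher, lower and tested, were: p53 targets 7, 15 and 25, G1/S 12, 10 and 27 (6 higher and 16 lower with gene totals only), repressors 11, 9 and 26, ribosome 18, 8 and 35, splicing 10, 11 and 33, glycolysis 8, 6 and 18, oxidative phosphorylation 8, 1 and 24, mitochondrial 4, 0 and 6, interferon 5, 4 and 14, epiblast 4, 6 and 13, endoderm 8, 4 and 14, trophectoderm 7, 5 and 17, neuroectoderm 4, 2 and 7, mesoderm 2, 4 and 10, fibroblast 6, 1 and 12, and blood 0, 2 and 4. Orc1 was 2.25-fold higher and Ccnd1, encoding cyclin D1, lower by a log2 fold change of -1.17 ± 0.07 within the G1/S list. Trim28 was 1.61-fold higher and Zfp809 6.46-fold higher, and Chaf1a and Dnmt1 did not pass, though both were lower with gene totals only (-0.37 and -0.35). In all, 5631 of 16403 genes were higher and 5252 lower, and with a 2-fold minimum 2784 and 1356. The largest falls included Msc, Zfp536, Pvt1, Gjb5 and Lefty2, a Nodal antagonist, from 24.9 ± 0.484 to 5.97 ± 0.613 CPM. With gene totals only the median of all genes lay at -0.25, and 4052 were higher and 7702 lower, 34.5% of calls higher against 51.7%.

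**Figure D2:**
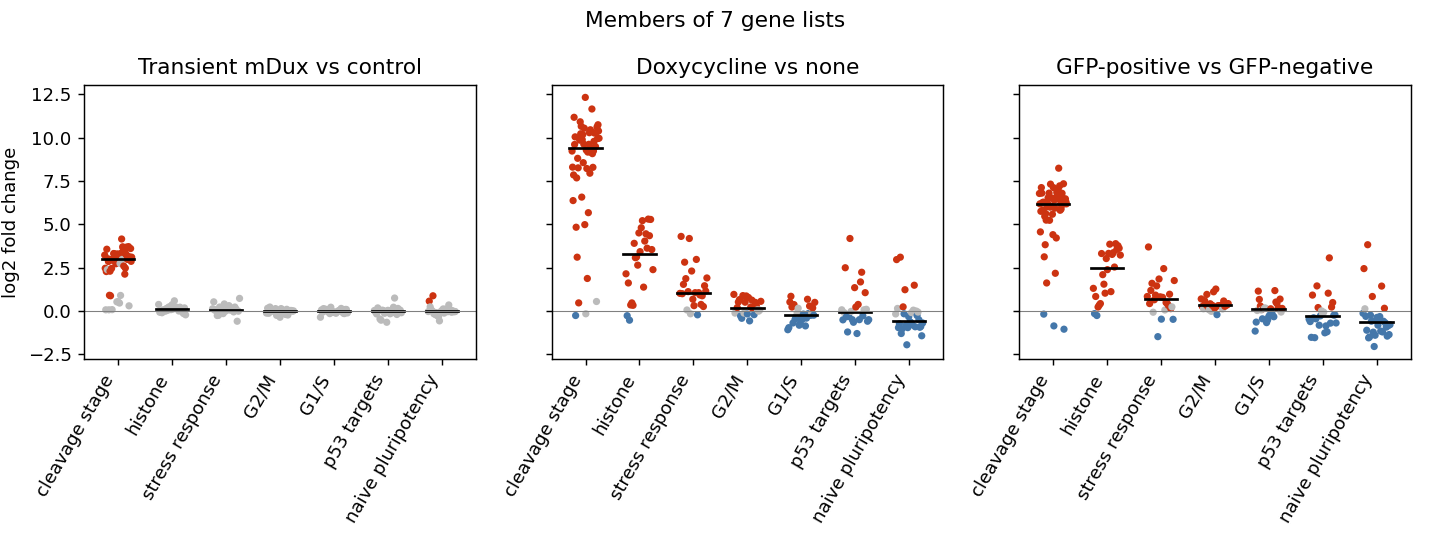
Log2 fold change of the tested members of 7 gene lists in the 3 main comparisons, red where higher, blue where lower and grey where not past the threshold, with black bars at the medians. The cleavage-stage medians were 2.97, 9.39 and 6.18.

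Repeat families rose along with these genes. MERVL-int, the internal part of the retrovirus used in the reporter, rose 9.19-fold in the transient comparison (261 ± 19.0 to 2400 ± 11.3 CPM), 358-fold with doxycycline (227 ± 13.1 to 81400 ± 1920 CPM), and was 96.3-fold higher in GFP-positive cells. Its long terminal repeat MT2_Mm rose 7.82-fold, 194-fold and 86.6-fold. Reads of both took 0.028% ± 0.00283 of counted reads in the transient control and 0.255% ± 0.00141 with mDUX, 0.0295% ± 0.00212 without and 6.07% ± 0.0516 with doxycycline, and 0.07% ± 0.00283 in GFP-negative and 4.82% ± 0.0148 in GFP-positive cells. ORR1A3-int rose 2.43-fold, 66.5-fold and 64.8-fold in the same order. In the transient comparison 51 of 1184 families rose and none fell, 42 of the 51 being LTR elements. Of all families tested there, 196 had an unadjusted p under 0.05 and DESeq2 called 1 lower. This count of families depended strongly on single libraries, as that of genes did.

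In the stable line most families of every large class rose: 1098 of 1273 with doxycycline, against 17 lower, and 1057 of 1233 in GFP-positive cells, against 19 lower. The median log2 fold changes over all families were 1.43 and 2.07. LTR families rose in 550 of 606 and 540 of 593 cases, LINE families in 140 of 153 and 137 of 149, and SINE families in 37 of 37 in both. The LINE family L1Md_T rose 5.91-fold and 4.65-fold, IAPEz-int 5.40-fold and 10.4-fold, the SINE B2_Mm2 2.55-fold and 3.22-fold, and the major satellite GSAT_MM 62.4-fold and 74.3-fold. The retroviral families ETnERV3-int (log2 fold change -0.67 ± 0.06 and -1.14 ± 0.09) and MMETn-int (-0.50 ± 0.06 and -0.60 ± 0.06) were lower.

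**Figure D3:**
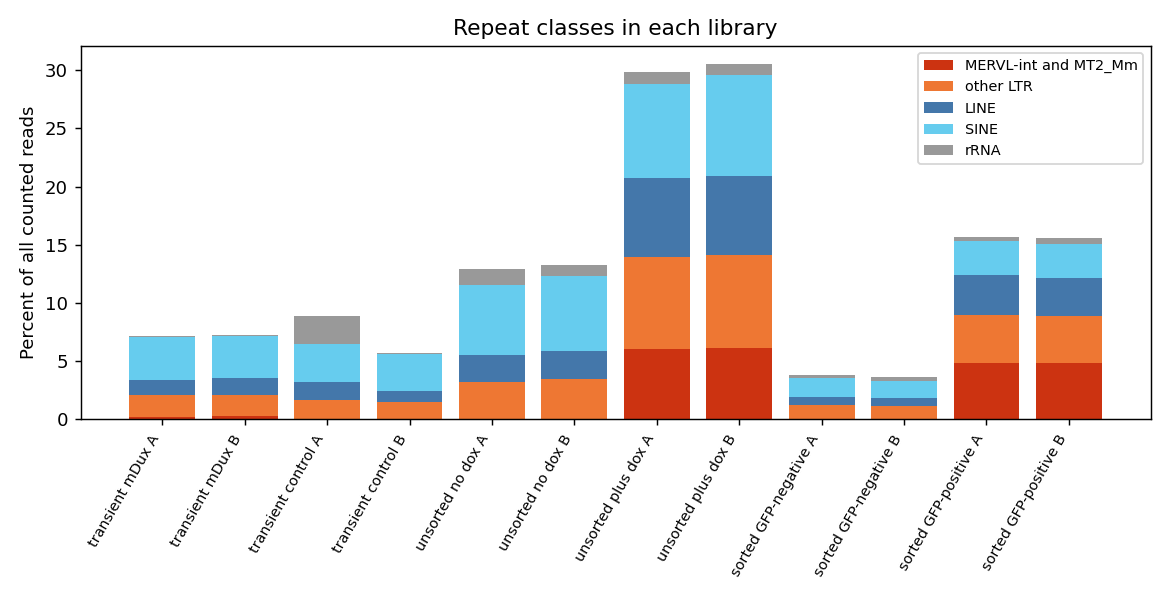
Percent of all counted reads in MERVL-int with MT2_Mm, other LTR, LINE, SINE and rRNA families, stacked, for each library. MERVL-int with MT2_Mm took 6.07% on average with doxycycline and 4.82% in GFP-positive cells.

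The main comparisons share no libraries, so their calls were set side by side. Of the 319 genes that rose in the transient comparison, 312 were tested in the unsorted comparison and 312 in the sorted comparison. All 312 rose in each, against 102 and 99.9 expected for independent lists (Fisher's exact test, one-sided, p = 5.18e-156 and 3.38e-158). In every one of them both induced libraries lay above both others by raw share of gene reads. Fisher's test treats genes as independent, while members of near-identical families are not, so its p-values do not measure the spread between libraries. Of transient genes with a positive fold change and an adjusted p from 0.2 to 0.5, 91.3% rose in the unsorted comparison, and of those at 0.5 or more 37.2% did. The 7 genes left out had too few reads or were absent, and 6 were left out of both: Gm5941, Gm14107, Gm4781, Gm25687, Gm21761, which neither table lists, and Hmgb1-ps8. The 5 listed ones had at most 6 reads in any stable-line library, so a rise there was not seen: Gm25687 had 103 and 107 reads with transient mDUX but 0, 1, 0 and 0 in the unsorted libraries and 0 in the sorted ones, and Gm4781 had 99 and 83 but at most 2. Cspg4 was left out of the unsorted comparison alone, with 4, 4, 3 and 0 reads, and Gm11525 of the sorted comparison alone. Without control A, 482 of 501 transient genes rose in the unsorted comparison, and without control B 744 of 1167. The median log2 fold change of the shared genes was 2.83 in the transient, 8.28 in the unsorted and 6.05 in the sorted comparison. Between the unsorted and sorted comparisons 3949 genes were higher in both, against 1820 expected. Log2 fold changes correlated across genes, which are not independent replicates, with Pearson's r of 0.74 between transient and unsorted, 0.90 between unsorted and sorted and 0.70 between transient and sorted, and with Spearman's rho of 0.28, 0.76 and 0.30.

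GFP-negative cells were last set against uninduced cells, in a different table. Of 57 cleavage-stage genes 48 were higher in GFP-negative cells, 1 (Patl2) was lower and 8 did not pass, with a median log2 fold change of 3.48. The camera adjusted p was 4.63e-05, and 0.264 with an estimated correlation. In that version the G1/S, ribosome and splicing lists passed (adjusted p = 0.0272 each) and no other list did. This fit held 8 libraries against 4 in each main comparison, so passes of that version cannot be compared between them. Zscan4d stood at 83.1 ± 7.28 CPM against 1.94 ± 0.464 CPM, and MERVL-int was 3.62-fold higher. Genes far from that list moved as well: 7768 of 17820 genes were higher and 6096 lower. Malat1 was 12.3-fold lower, Gapdh 8.89-fold higher, 27 of 27 G1/S genes were higher, and 1208 of 1321 repeat families lower. Mitochondrial genes were at 0 reads in the unsorted table and took 0.496% ± 0.0251 of gene reads in GFP-negative cells. The table and the cell group cannot be told apart in this comparison, and with gene totals only 5069 genes were higher and 9117 lower.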

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

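The tests of the GFP-negative, histone and repeat patterns were chosen after those patterns were seen, and the bounds of the repeat tests were set before those tests were run. Effects were compared by interaction tests with edgeR's quasi-likelihood test.

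The transient and unsorted effects differed for 6307 of 17152 genes. MERVL-int and MT2_Mm rose less in the transient set, by log2 differences of -5.10 and -4.45. The largest negative differences were those of Gm17026 (-12.16), Gm9573 (-11.94), Obox4-ps12 (-11.51), Gm12394 (-11.0) and Gm11238 (-9.80), and the largest positive ones those of Cspg4 (7.41), Gm14928 (4.56), Gm13675 (4.40), Gm16089 (4.15) and Grin2b (3.03). Groups at or near 0 reads enter all of these genes, so the fitted values depend on the prior count and are not bounds. Read length and library set differ along with the mode of expression.

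The sorted and unsorted effects differed for 5429 of 17820 genes. MERVL-int and MT2_Mm differed by -1.98 and -1.25. The largest negative differences were those of Gm9573 (-6.92), Gm22112 (-6.79), Fam90a1a (-6.73), Gm11238 (-6.48) and Gm11487 (-6.32), and the largest positive ones those of Gm5380 (6.54), Cspg4 (6.21), Gm5946 (5.82), Gm12475 (4.91) and Gm15720 (4.73). All 5 negative genes had 0 reads without doxycycline, Gm5380 and Gm5946 had 0 in GFP-negative cells, and the other 3 had a group near 0, so these values and their order depend on the prior count and are not bounds. The direction split was not stable: 32.4% of the calls were positive with TMM, 54.8% with RLE size factors, 78.8% with TMM over genes and repeats together, and 70.4% and 68.4% without GFP-positive library A or B.

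Repeat families rose almost throughout in the stable line. Scaling on gene counts only was tested with TMM over genes and repeats together, where the smaller of the 2 medians was still 1.38. With 16229 genes against 1273 families, genes set that scaling too, so the test cannot decide. As shares of all counted reads, LTR families went from 3.34% without doxycycline to 14.0% with it. LINE families went from 2.38% to 6.8%, SINE families from 6.21% to 8.38% and rRNA families from 1.18% to 0.983%. These shares do not use gene counts for scaling. A response that the separately made transient libraries share was tested by the Spearman correlation across families between transient and unsorted fold changes, 0.55 (Pearson's r 0.51). Families thus ranked partly alike. A correlation does not register a shift of all families, and the median log2 fold change was 0.16 in the transient set against 1.43 with doxycycline. It therefore does not show that the rise of nearly all families was shared. Genomic DNA in the induced libraries stays open for families other than MERVL: the gain per megabase spread 5.13-fold between the 10th and 90th percentiles, between the bounds of 3 and 10.

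Cleavage-stage genes stood above the uninduced level in GFP-negative cells. Carry-over of GFP-positive cells as the only source stays open. Over 53 genes near 0 without doxycycline, the GFP-negative level was 1.06% of the GFP-positive level in the median, and its 90th percentile was 2.47 times its 10th. A first version over 64 genes gave 97.5, and 2.50 without 8 mitochondrial genes at 0 in the unsorted table; genes not called higher with doxycycline were then left out, which dropped 3 others too (5730507C01Rik, B020031M17Rik and Gm16429); over 12 choices of genes and limits the ratio ran from 1.36 to 5.04, with 3 at or under 2 and 4 at or over 3. The uninduced baseline is argued against on the condition that list genes were induced as strongly in the sorted set. A factor of each gene that differs between the tables drops out of the sorted effect minus the unsorted effect, and at baseline that difference would not be negative unless induction was weaker in the sorted set. Over the list its median ran from -3.25 to -2.77 in 15 fits, with the unsorted effect larger for 45 of 57 members and the sorted effect larger for 2. Over 442 genes off the list that rose 2-fold or more with doxycycline from at least 10 CPM it ran from -0.29 to 0.09, so induction was not weaker throughout. These genes started from higher levels than list genes such as Zscan4d, at 2.35 CPM without doxycycline. They therefore do not show that list genes were induced alike in both sets. Weak induction without GFP was not tested and stays open.

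Histone genes rose in the stable line and did not pass in the transient set. The transient effect was smaller for 19 of 25 members by the interaction test. Replication-dependent histone genes reached 348 ± 29.2 CPM with doxycycline, below the SD of 605 CPM between the transient controls. A rise of that size in CPM could not be seen there, so the interaction does not show that mDUX acted less on these genes. The G1/S list gave no sign of more cells in S phase: its medians were -0.25 with doxycycline and 0.12 in GFP-positive cells. Levels of these transcripts do not measure the share of cells in S phase, so the test cannot exclude a shift in it. Scaling is argued against by a histone median of 2.21 or more with gene totals only. A change in the polyadenylated minority of histone transcripts stays open. The list took 3.79 times the share of gene reads in the transient control that it took in uninduced cells, between the bounds of 3 and 10. That ratio rests largely on other members: in uninduced cells the list took 1050 ± 20.4 CPM and all replication-dependent histone genes 31.4 ± 7.08 CPM. These genes took 4740 ± 605 CPM in the transient control. That far wider gap goes with this explanation but does not establish it, as the sets differ in other ways. S phase was the only biological explanation tested for this pattern.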

How the results depend on the processing

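The scalings by gene totals only and by TMM over genes and repeats together, the replicate block, the 2-fold minimum outside the main comparisons, and all alternatives for repeat families, were chosen after seeing the data. Counts of genes and of repeat families within 1.5 times of those reported are not listed. Of 46 counts of list members per comparison, 12 in the transient, 27 in the unsorted and 23 in the sorted comparison stayed within that bound throughout, and of named genes 27 of 43, 57 of 60 and 59 of 65 kept their call and sign. In the transient comparison, genes lower numbered 2 with DESeq2 and 91 with no filter; repeat families lower numbered 1 with DESeq2, and families higher 164 with no filter and 29 with a 2-fold minimum. Leaving out each library in turn gave 247 to 1185 genes higher and 0 to 1404 lower, and 16 to 555 repeat families higher and 0 to 35 lower. In the unsorted comparison, a 2-fold minimum left 2636 genes higher, 953 lower and 5 repeat families lower. Repeat families lower numbered 5 with DESeq2, 29 with gene totals only, and 11 to 13 leaving out each library. In the sorted comparison, a 2-fold minimum left 2784 genes higher, 1356 lower and 4 repeat families lower, and repeat families lower numbered 43 with gene totals only and 32 with one spread over the 8 stable-line libraries. For GFP-negative against uninduced cells, a 2-fold minimum left 4554 genes higher, 3786 lower and 5 repeat families higher, gene totals only gave 5069 genes and 5 repeat families higher, and repeat families higher numbered 12 with RLE size factors, 8 with DESeq2 and 12 with TMM over genes and repeats together. With a 2-fold minimum, the sorted and unsorted effects differed for 1492 genes and 186 repeat families, and the transient and unsorted effects for 2835 genes. The overlap of genes higher in the unsorted and sorted comparisons was 1908 with a 2-fold minimum. With gene totals only, the sign reversed for Chaf1a (-0.13) and Mdm2 (-0.0) in the unsorted comparison and for Uhrf1 (-0.11) in the sorted comparison. The planned block by title number was not run, since columns carry an index that is not tied to it. With that index as a replicate block, 389 genes rose and 40 fell in the transient comparison, with 115 repeat families higher, and no other count of genes or families moved so far. The libraries share only the index: differences between libraries A and B correlated across genes at -0.22, -0.06 and -0.08 between the groups of the transient, unsorted and sorted tables. With the index crossed in the transient comparison, 400 genes rose and 14 fell, and 149 repeat families rose. The GFP-negative against uninduced comparison was not blocked, as it runs between tables. A library left alone in its group was assumed to vary like the others.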

Other observations

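Gene families were counted with no test of enrichment, chosen after their values were seen; the cleavage-stage list already holds 5 Tdpoz, 3 Pramef and 2 Obox genes and Olfr376. All 30 tested Obox genes, homeobox genes of the oocyte and early embryo, were higher in both stable-line comparisons, with median log2 fold changes of 8.19 and 5.93, and 3 of 4 rose in the transient comparison. All 3 tested Tdpoz genes rose in every main comparison. Of Pramel and Pramef genes 2 of 9 rose in the transient set, 9 of 9 rose with doxycycline, and 9 of 10 were higher and 1 lower in GFP-positive cells. Olfactory receptor genes, active in the nose, rose in 26 of 33 tested cases and fell in 6 with doxycycline. They were higher in 24 of 27 tested cases and lower in 2 in GFP-positive cells. In the stable line 267 olfactory receptor genes were counted, so most had too few reads to be tested. A gene with reads only after induction passes the filter, so the tested members of all these families lean towards genes that rose. Vomeronasal receptor genes (Vmn) rose in 2 of 5 transient cases, in 8 of 12 with doxycycline and in 8 of 11 in GFP-positive cells, with 0 lower in each. Zinc finger genes named Zfp, whose domains were not checked, and Trim genes went both ways in the stable line. Of these Zfp genes 6 of 339 rose and 0 fell in the transient set. With doxycycline 121 rose and 113 fell of 340, and 110 were higher and 143 lower of 346 in GFP-positive cells. Of Trim genes, in the same order, 1 of 42 rose and 0 fell, 25 rose and 12 fell of 49, and 20 were higher and 14 lower of 48. Reads of near-identical members are shared in a way not given in the sources used here.

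Cspg4 rose in the transient set and was higher in GFP-positive cells, at 48.5 against 1.02 CPM in the joint fit, while the unsorted table held 4, 4, 3 and 0 reads for it over its 4 libraries. Mitochondrial genes were at 0 in the unsorted table and not in the others. Replication-dependent histone genes and Rmrp, a noncoding RNA, took 4740 ± 605 and 2280 ± 479 CPM in the transient control against 31.4 ± 7.08 and 21.8 ± 18.5 CPM in uninduced cells, so the transient and stable-line libraries differ in more than the mode of expression.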
